A study of Mus musculus with 4 samples.

How the data were processed

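Single-cell RNA sequencing libraries of CD45+ cells sorted from subcutaneous 499 tumors, 2 from WT and 2 from IFNgR KO tumors, all taken on day 17 from B6 WT mice, were analysed. Per the labels, the libraries were made with the droplet-based tag kit of version 2. The submitters' processing notes name bcl2fastq for base calls and Cell Ranger with the mm10 genome for alignment and counting. The deposited files hold counts: UMIs per gene and barcode, already limited by the authors to called cells, as the lowest total of any barcode was 841, 926, 898 and 831 UMIs. Each library comes with 2 sets of matrix files, which were identical in 4 of 4 libraries, so 1 set was used. Of 28692 gene IDs, 28339 (98.8%) matched GENCODE M21, the source of the coordinates; 67 duplicated symbols were told apart by ID. Raw reads were not analysed here.

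Barcodes were kept with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs, where 6, 12, 14 and 5 barcodes of WT 1, WT 2, IFNgR KO 1 and IFNgR KO 2 failed the mitochondrial limit. Scrublet in scanpy 1.11.5 scored doublets per library, and the highest-scoring 0.8% per 1000 barcodes were removed (99, 87, 34 and 176; some barcodes failed more than one filter), where its automatic threshold called 3, 1, 0 and 1. The kept cells had medians of 2012.5, 2155, 2334.5 and 2081 UMIs, and all barcodes medians of 764, 828.5, 866 and 829.5 genes and 2.47%, 1.87%, 2.04% and 1.77% mitochondrial UMIs. Counts were scaled to 10000 per cell and log-transformed. From 2000 variable genes chosen with the library as batch, without interferon, proliferation, antigen receptor, mitochondrial, ribosomal and sex-linked genes, 30 principal components and 15 neighbours were computed with no batch integration. Leiden clustering (igraph 0.11.9, resolution 1.0) kept the partition of highest modularity among 10 seeds. Clusters with raised T cell markers (mean log2 difference of at least 0.5) were pooled and clustered again on their own variable genes at a resolution of 2.0. A cluster with melanoma and macrophage markers was split at a resolution of 0.5. Both steps were chosen after seeing the data. Clusters were named by fixed marker genes (at least 3 raised by 1 log2 unit) as "-like" classes; those without such markers were named by their leading genes. Free RNA was not subtracted. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.

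Counts were summed per library over all kept cells and over each class with at least 20 cells in every library (13 of 17 classes). Each sum was tested between groups in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM, robust quasi-likelihood fit, group as the only term), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The libraries, not the cells, are the replicates. Errors beside group means are SDs over 2 libraries. Those beside log2 changes (IFNgR KO minus WT) are approximate standard errors (SE), calculated as the size of the log2 change over the square root of the test's F statistic. Shares of 15 classes with at least 10 cells per library on average were tested with edgeR on cell counts and with a two-sided exact permutation test, whose smallest p for this design is 0.333. Intervals of single shares are 95% exact (Clopper-Pearson) intervals and cover counting error only. Fixed gene lists (23, with 398 genes in the files) were tested where at least 5 members were tested, with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), beside an estimated correlation and fry. Marker genes of cell types were tested as lists with the preset correlation only. The difference of the group effect between T cells and monocyte-like and macrophage-like cells was tested in edgeR with the library as block.

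The tests, thresholds, gene lists and markers, and the rule for named genes, were set before the data were examined. By that rule Ifngr1, Ifngr2, Ifng, Irf1, Pdcd1, Cd274 and Cxcl9 are always candidates. Some genes picked by the rule are not reported here, nor counted among the comparisons with alternatives. In the sum of all cells and the 3 largest classes it adds the 10 genes in each direction with the smallest adjusted p among those past the threshold whose groups do not overlap, or up to 5 of the smallest p where fewer passed. In other classes it adds 3 in each direction, and from each list up to 4 members; unnamed gene models and antigen receptor segments are skipped. Transcripts alike in every class and Igkc were chosen after their values were seen.

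Libraries of the same group differed far beyond counting noise over genes with at least 10 counts (chi-square per degree of freedom 11.1 in WT and 16.0 in IFNgR KO). The pipeline was tested on simulated data made from these counts, with 200 genes changed. A change of 4-fold was recovered in 92.4% of changed genes in the sum of all cells, 98.5% in macrophage-like and 89.4% in monocyte-like cells, and a change of 2-fold in 40.3%, 64.2% and 56.7%, with 12, 15 and 2 false calls. For the difference between compartments these shares were 68.2% and 8.96%, with 9 false calls. A list shifted by 1 log2 unit was called by camera and missed with an estimated correlation (camera adjusted p = 0.105). The simulated genes were drawn independently, so this does not test camera's false calls where list members are correlated.

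Alternatives were other scalings (edgeR's RLE, library sizes only), DESeq2 1.42.0, other filters on low counts, the replicate number as a block, leaving out each library, other cell filters, thinning to the same mean UMIs per cell in every library, other clusterings, other denominators of shares and other list tests. DESeq2 was not run on lists or shares. No sample was left out. Classes with fewer cells were left out of the gene tests.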

Results

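CD45+ cells, the leukocytes of a tumor, were collected by flow sorting from subcutaneous 499 tumors grown in B6 WT mice for 17 days, and their transcripts were counted by droplet-based single-cell RNA sequencing with unique molecular identifiers (UMIs). The tumor cells were WT or lacked the interferon-gamma receptor (IFNgR KO). Each group has 2 libraries. Since the hosts were WT, the comparison addresses how immune cells differ when the tumor around them cannot sense interferon-gamma, a cytokine secreted by T and NK cells. The labels give melanocyte as the source of every sample, whereas 27 of the 13137 kept cells carried melanoma markers. The deposited counts comprised 3515 barcodes with 9717794 UMIs in WT 1, 3300 with 9302154 in WT 2, 2062 with 6645291 in IFNgR KO 1 and 4690 with 12351406 in IFNgR KO 2. After filtering, 3410, 3203, 2014 and 4510 cells remained, with medians of 2012.5, 2155, 2334.5 and 2081 UMIs per cell. The labels do not state that the libraries of a group come from separate animals, so each p-value measures the spread between these samples, which may be technical. With 1 library left out, 1 group holds a single library and the spread comes from the other group alone. Calls gained in such fits are no support for genes that failed with all libraries. For those genes, values are given below only from the fits in which they then passed. Such values are therefore selected and do not show how stable the change was.

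The receptor chains themselves were read first. Ifngr1 (ENSMUSG00000020009; chromosome 10, 19591949 to 19610229 in mm10 coordinates), which encodes the ligand-binding chain, stood at 225, 293, 265 and 324 CPM (depth-scaled counts) in the summed cells of WT 1, WT 2, IFNgR KO 1 and IFNgR KO 2. Its mean was 259 ± 47.4 CPM in WT and 294 ± 41.7 in IFNgR KO (SD, n = 2), a log2 change of 0.19 ± 0.18 (SE) with an edgeR adjusted p of 0.980. Ifngr2 (ENSMUSG00000022965; chromosome 16, 91547072 to 91565623), the signaling chain, had 85.0, 74.8, 58.5 and 68.6 CPM and a log2 change of -0.33 ± 0.15 (adjusted p = 0.980). Within single cell classes the change of Ifngr1 ranged from -0.84 to 0.40 over 13 classes (smallest edgeR adjusted p = 0.428, in migratory dendritic-like cells). There it stood at -1.76 without IFNgR KO 1. The change of Ifngr2 ranged from -0.26 to 0.05 over 8 classes (smallest 0.954). These are host cells, so the values do not check the tumor genotype. The 27 melanoma-like cells held 7, 0, 3 and 1 Ifngr1 UMIs in the order of the libraries, and a tag at the transcript end checks no edit elsewhere in the gene.

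Clustering divided the kept cells into 33 clusters, which marker genes sorted into 17 classes. B-like cells, marked by Cd79a and Ms4a1, and macrophage-like cells, marked by the complement gene C1qb and by Cd68, were the most frequent classes with 2139 and 2032 cells. Macrophage-like cells made up 18.4 ± 1.45% of kept cells in WT and 12.5 ± 0.302% in IFNgR KO, and monocyte-like cells, marked by Ly6c2 and Ccr2, 10.9 ± 0.330% and 7.60 ± 0.984% (SD, n = 2). In both classes the libraries of the groups did not overlap, which chance gives in 0.333 of comparisons, so 5 of the 15 shares tested would be apart by chance where 2 were. Neither share passed the test (log2 change -0.56 ± 0.47 and -0.52 ± 0.47, edgeR adjusted p = 0.944 for both, exact permutation p = 0.333, the smallest that 2 against 2 libraries allow). CD8 T-like cells, marked by Cd8a and Cd8b1, took 6.66% of WT 1 (exact 95% interval 5.84 to 7.55), 3.93% of WT 2 (3.29 to 4.67), 5.56% of IFNgR KO 1 (4.60 to 6.65) and 23.1% of IFNgR KO 2 (21.9 to 24.3), so 1 library carried the higher mean of that group. Regulatory T-like cells, marked by Foxp3 and Ikzf2, took 6.10%, 18.7%, 18.2% and 5.25%, with larger differences inside the groups than between them (log2 change -0.08 ± 0.85). None of the 15 shares passed edgeR's test, and none had an unadjusted p under 0.05; DESeq2 was not run on shares.

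**Figure D1:**
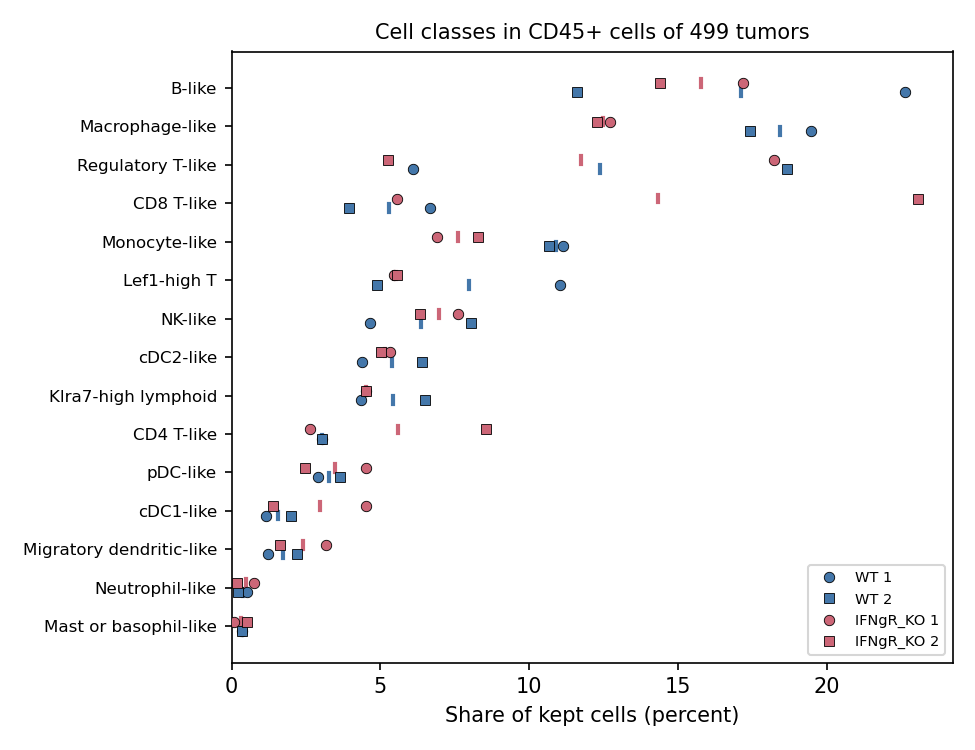
Share of kept cells (percent, horizontal axis) of each cell class in the 2 WT libraries (blue) and the 2 IFNgR KO libraries (red); vertical ticks mark group means. Macrophage-like cells lie at 12.7% and 12.3% in IFNgR KO against 19.5% and 17.4% in WT, and CD8 T-like cells at 23.1% in a single IFNgR KO library.

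Summing all kept cells joins changes in cell makeup with changes inside cells. No gene passed edgeR's test in that sum. Among the genes with the smallest p-values, Chil3, a chitinase-like protein of monocytes and alternatively activated macrophages, went from 183 ± 13.1 to 67.1 ± 3.55 CPM (log2 change -1.44 ± 0.14, adjusted p = 0.183), and Pdpn, which encodes the membrane glycoprotein podoplanin, from 12.5 ± 0.154 to 2.05 ± 0.908 CPM (-2.51 ± 0.30, adjusted p = 0.345; SD, n = 2). Nr4a2, an activation-induced nuclear receptor, had a log2 change of -1.13 ± 0.15, the choline kinase gene Chka -1.09 ± 0.15 and the heat shock gene Hspa1a -1.24 ± 0.18. On the other side stood Asap2 (1.36 ± 0.25), the RNA exosome gene Exosc2 (0.81 ± 0.16), Slamf7, a receptor of cytotoxic and myeloid cells (0.74 ± 0.15), and the protease inhibitor genes Serpinb6b (0.78 ± 0.14) and Serpinb9 (0.77 ± 0.17). With edgeR 0 of 11440 genes passed, 557 had an unadjusted p under 0.05, and DESeq2 called 29. Without IFNgR KO 1 Chil3 stood at -1.39, Pdpn at -2.20, Nr4a2 at -1.17, Chka at -1.07 and Hspa1a at -1.36. Asap2 then stood at 1.25, Exosc2 at 0.93, Slamf7 at 0.85, Serpinb6b at 0.68 and Cxcl9 at 1.69. Without IFNgR KO 2 the values were -1.50 for Chil3, -3.13 for Pdpn, -1.09 for Nr4a2, -1.11 for Chka and -1.12 for Hspa1a. They were 1.48 for Asap2, 0.87 for Serpinb6b and 0.88 for Serpinb9. Among the other genes read in every sum, Irf1, a transcription factor gene that interferons induce, had a log2 change of 0.29 ± 0.25. The chemokine gene Cxcl9 stood at 1.08 ± 0.64, Ifng itself at -0.52 ± 0.65, and the checkpoint genes Pdcd1 and Cd274 at 0.08 ± 0.39 and -0.12 ± 0.18 (each adjusted p at least 0.980).

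Of the 23 fixed gene lists, 9 were called in the sum of all cells by camera with a preset correlation, and none with an estimated correlation (adjusted p = 0.736 for each with an estimated correlation). Type I interferon-stimulated genes (33 of 39 members above 0, median log2 change 0.28), interferon-gamma response genes (29 of 33, 0.47), MHC class I antigen presentation (19 of 20, 0.31) and proliferation (24 of 25, 0.32) were called higher. Inflammatory myeloid genes (median -0.83), alternatively activated macrophage genes (-0.43), complement and lipid-handling macrophage genes (-0.45), hypoxia and glycolysis (-0.19) and dissociation and immediate early genes (-0.70) were called lower. No member passed over all genes tested; adjusted over the list alone, 10 of 19 immediate early genes, 8 of 16 inflammatory genes, 5 of 16 alternatively activated and 4 of 19 complement and lipid-handling genes were lower. Among marker genes of cell types, those of migratory dendritic cells (median 0.46, adjusted p = 0.00158), T cells (0.42, 0.0121), plasma cells (0.69, 0.0129), CD8 T cells (0.93, 0.0252) and cDC1 (0.46, 0.0252) were called higher. Those of macrophages (-0.77, 2.06e-08), monocytes (-0.14, 0.0252) and melanoma cells (-0.54, 0.0419) were called lower. Without CD8 T-like cells the marker calls ended for T cells (median 0.06, camera adjusted p = 0.380) and CD8 T cells (0.17, 0.280). They also ended for monocytes (-0.01, 0.102) and melanoma cells (-0.40, 0.245). Those of migratory dendritic cells, plasma cells, cDC1 and macrophages stayed, with medians of 0.50, 0.86, 0.56 and -0.64. Markers of NK cells, cDC2 and pDC were called higher only there. Of the 23 fixed lists 8 were called in that sum. The calls ended without IFNgR KO 2 for type I interferon (median -0.06), interferon-gamma (0.11), MHC class I (0.13), alternatively activated (-0.32) and hypoxia genes (-0.04). Without WT 1 those of hypoxia (-0.01) and proliferation (-0.01) ended, and the interferon-gamma and immediate early medians were 0.30 and -0.45. Without IFNgR KO 1 the proliferation call ended (0.04), and medians were 0.48 for type I interferon, 0.48 for MHC class I, -0.55 for inflammatory, -0.80 for alternatively activated and -0.37 for hypoxia genes. Without WT 2 they were 0.50 for MHC class I, 0.69 for proliferation and -0.35 for hypoxia genes.

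Macrophage-like cells had 27 transcripts higher and 25 lower in IFNgR KO among 7666 tested (edgeR). With all variable genes used for clustering 9 passed, each of them among these. Genes of antigen presentation and of the interferon response rose: H2-Ab1, an MHC class II chain, from 1511 ± 25.0 to 2642 ± 45.4 CPM (log2 change 0.81 ± 0.12, adjusted p = 0.00177), and Isg15, a ubiquitin-like protein induced by interferon, from 119 ± 23.1 to 255 ± 11.1 CPM (1.10 ± 0.17, 0.00224; SD, n = 2). The guanylate-binding protein gene Gbp7 (1.65 ± 0.27) and the immunoproteasome genes Psmb8 (0.88 ± 0.15) and Psmb9 (1.10 ± 0.19) rose with them. S100a9, a calcium-binding protein of neutrophils, rose from 2.55 ± 0.389 to 28.6 ± 2.53 CPM (3.45 ± 0.39, adjusted p = 2.37e-04), with its partner S100a8 (2.84 ± 0.30). Ly6c2, a surface antigen of monocytes, rose from 239 ± 7.36 to 499 ± 93.8 CPM (1.06 ± 0.15), as did its relative Ly6i (1.95 ± 0.25) and the serpin gene Serpina3g (1.95 ± 0.34). Arg1, the arginase of alternatively activated macrophages, fell from 523 ± 84.3 to 244 ± 4.88 CPM (-1.10 ± 0.15, 8.18e-04), and Chil3 from 417 ± 88.3 to 194 ± 5.88 CPM (-1.10 ± 0.16, 0.00162). Pdpn (-2.29 ± 0.28), Gpnmb, a glycoprotein of lipid-laden macrophages (-1.30 ± 0.20), the kinase gene Sgk1 (-2.05 ± 0.25), the stress-response gene Ppp1r15a (-1.46 ± 0.21), Emp1 (-1.02 ± 0.18), Chka (-1.60 ± 0.28) and Syngr1 (-2.33 ± 0.28) fell too. Sox4, a transcription factor gene, had 7.60 ± 2.76 CPM in WT and no UMI in either IFNgR KO library (adjusted p = 0.0156).

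Several of these calls rest on few libraries, and clusters inside the class differed in share. Cxcl9 (1.74 ± 0.52, adjusted p = 0.459), Irf1 (0.80 ± 0.31, 0.410), Ifngr1 (0.40 ± 0.18, 0.526), Ifngr2 (-0.06 ± 0.20, 0.979) and Cd274 (-0.14 ± 0.21, 0.922) did not pass in macrophage-like cells. Without IFNgR KO 1, Cxcl9 (2.19) and Irf1 (1.15) did. Macrophage markers were lower as a group by camera with the preset correlation (median -0.36, adjusted p = 0.0333), as in cluster 9 (-0.27, 0.0352) but not in cluster 4 (0.10, 8 of 14 above 0, 0.912). Markers of cDC1 (0.52, 0.00648, with 2 past the threshold over all genes) and of neutrophils, which include S100a8 and S100a9 (0.38, 0.0202), were higher. Those of monocytes were not called (0.33, 0.229). Syngr1 is also a melanoma marker, and Gpnmb was a leading gene of the melanoma-like cells. Cluster 9, whose leading gene was Arg1, made up 40.7% and 34.1% of the class in WT and 28.9% and 20.8% in IFNgR KO. Arg1 had a log2 change of -0.44 ± 0.22 inside cluster 4 and -0.60 ± 0.14 inside cluster 9, neither past the threshold, whereas Chil3 fell in both (-1.30 ± 0.18 and -1.17 ± 0.21). Gpnmb (-0.55 ± 0.42 and -0.60 ± 0.18) and Cd63, a lysosomal tetraspanin (-0.07 ± 0.24 and -0.95 ± 0.19), passed in neither cluster. S100a9, Syngr1 and Sox4 were not tested in cluster 4 or cluster 9. Without WT 1, 20 genes passed, and the calls ended for H2-Ab1 (0.81), Isg15 (0.90), Gbp7 (1.64), Psmb8 (0.87), Psmb9 (0.91), Ly6c2 (1.02), Arg1 (-0.94) and Emp1 (-0.83). Without WT 2 they ended for H2-Ab1 (0.78), Psmb8 (0.87), Serpina3g (1.61), Chil3 (-0.88) and Chka (-1.48), and without IFNgR KO 2 for Gbp7 (1.24), Serpina3g (1.58) and Sox4. The count was 297 without IFNgR KO 1 and 96 without IFNgR KO 2, and DESeq2 called 24 genes, 21 of them among the 52.

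Fixed lists of interferon-related genes were called higher in macrophage-like cells by camera with a preset correlation only. Of 28 interferon-gamma response genes 25 lay above 0, with a median log2 change of 0.95 (adjusted p = 4.93e-12, and 0.412 with an estimated correlation); 5 passed over all genes and 14 adjusted over the list alone, among them Gbp4 (1.88 ± 0.39). Type I interferon-stimulated genes had a median of 0.65 (31 of 35 above 0; 4 passed over all genes and 20 adjusted over the list alone), with Slfn1 at 1.02 ± 0.19 and Irf7, the regulator of interferon production, at 0.86 ± 0.18. MHC class I genes had a median of 0.58 (19 of 19 above 0; 4 passed over all genes and 10 adjusted over the list alone), with H2-T23 at 0.97 ± 0.18 and H2-K1 at 0.68 ± 0.14. For MHC class II genes it was 0.59 (9 of 9; 2 and 6), with H2-Eb1 at 0.59 ± 0.13. Inflammatory myeloid genes were called lower (median -0.61; 1 of 13 passed over all genes and 4 adjusted over the list alone), led by the neutrophil-attracting chemokine gene Cxcl3 (-1.32 ± 0.24). So were complement and lipid-handling genes (-0.33; 2 and 6 of 19), with the tetraspanin gene Cd63 at -0.86 ± 0.17, and immediate early genes (-0.67; 1 and 8 of 19), with the phosphatase gene Dusp1 at -0.75 ± 0.17. Cxcl3, a leading gene of cluster 9, passed in neither cluster (0.25 ± 0.39 in cluster 4 and -0.76 ± 0.50 in cluster 9). Alternatively activated macrophage genes were not called (median -0.09, camera adjusted p = 0.0702). Smaller shifts were called for oxidative phosphorylation (0.13, higher) and, lower, for checkpoint ligands and costimulation (-0.24), hypoxia and glycolysis (-0.20) and ribosomal protein genes (-0.18). None of the 11 calls held with an estimated correlation (adjusted p = 0.412 with an estimated correlation, except 0.423 for inflammatory and 0.710 for hypoxia and ribosomal protein genes). The interferon-gamma median was 0.36 without IFNgR KO 2 and 1.24 without IFNgR KO 1. Without WT 1 the inflammatory (-0.34), checkpoint (-0.21), hypoxia (-0.07), oxidative phosphorylation (0.12) and ribosomal (-0.13) calls ended. The complement and lipid-handling median was then -0.57 and the immediate early median -0.41. Without WT 2 the oxidative phosphorylation call ended (0.12), and the checkpoint and hypoxia medians were -0.39 and -0.34. Without IFNgR KO 1 the checkpoint (-0.29) and oxidative phosphorylation (0.13) calls ended, and the complement and lipid-handling and the hypoxia medians were -0.60 and -0.37. Without IFNgR KO 2 the hypoxia (-0.11), oxidative phosphorylation (0.15) and ribosomal (-0.12) calls ended. Among the members named here, Slfn1, Irf7, H2-T23, H2-K1, H2-Eb1, Gbp4 and Dusp1 no longer passed without WT 1 (1.00, 1.00, 0.98, 0.58, 0.64, 2.08 and -0.57) nor without WT 2 (1.01, 0.72, 0.93, 0.77, 0.52, 1.71 and -0.93). Cxcl3 did not pass without WT 1 (-1.22), Cd63 without WT 2 (-0.69) and Gbp4 without IFNgR KO 2 (1.35).

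**Figure D2:**
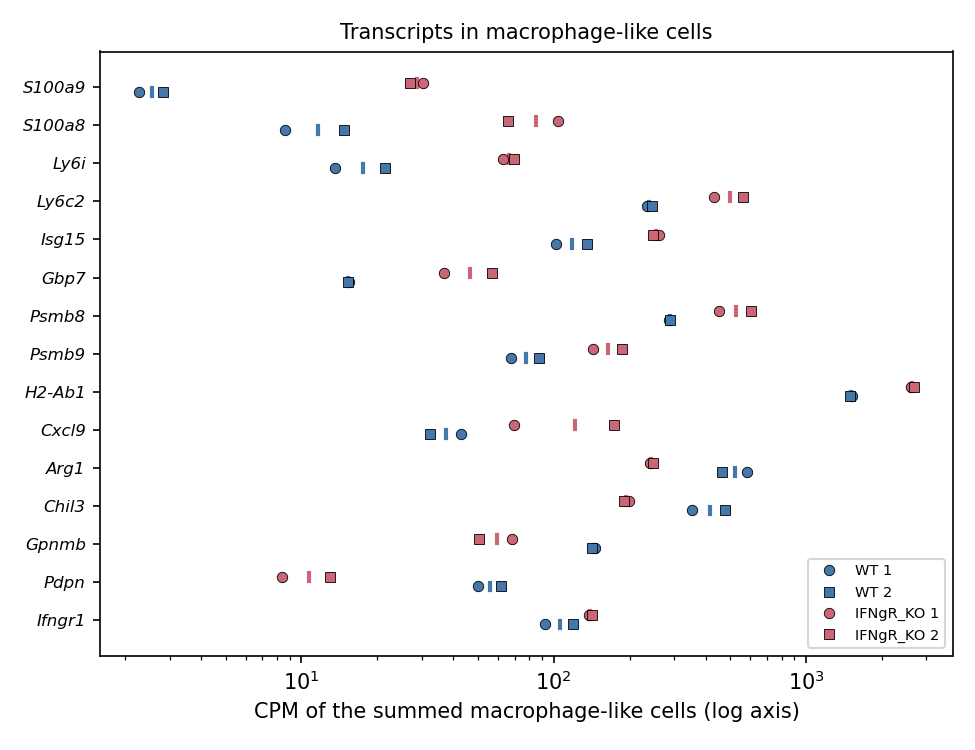
CPM (log axis) of 15 transcripts in the summed macrophage-like cells of the 2 WT libraries (blue) and the 2 IFNgR KO libraries (red); vertical ticks mark group means. S100a9 averages 2.55 CPM in WT and 28.6 in IFNgR KO, and Arg1 523 and 244, whereas Ifngr1 and Cxcl9 did not pass the test.

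Monocyte-like cells had 21 transcripts higher and 16 lower among 5989 tested. Of the 10 monocyte markers 3 passed as lower, Chil3 among them, and 4 lay above 0 (camera adjusted p = 0.217 for the group). At a clustering resolution of 2.0, 11 genes passed. A change in the makeup of the class was not tested. Ddit4, an inhibitor of mTOR induced by stress and glucocorticoids, rose from 31.3 ± 3.90 to 118 ± 1.18 CPM (log2 change 1.92 ± 0.24, adjusted p = 3.28e-08; SD, n = 2). Fcgr4, an activating Fc receptor of nonclassical monocytes, rose from 57.4 ± 8.02 to 152 ± 40.4 CPM (1.35 ± 0.22, 3.14e-05), and Bcl2a1a, a survival factor of the BCL2 family, by 1.53 ± 0.26. Chil3 fell from 856 ± 4.48 to 467 ± 120 CPM (-0.91 ± 0.14, 2.59e-05), the kinase gene Pim1 by 0.79 ± 0.15 on the log2 scale, and Fos, a subunit of the AP-1 transcription factor, from 853 ± 153 to 546 ± 4.11 CPM (0.00385). Among members of the lists, the MHC class I genes H2-K1 (0.64 ± 0.14), H2-Q7 (1.35 ± 0.30) and H2-D1 (0.46 ± 0.12) rose, as did the tetraspanin gene Cd9 (1.35 ± 0.24), Bcl2a1b (1.27 ± 0.23) and the NF-kB inhibitor gene Nfkbia (0.68 ± 0.14), and the mitochondrial gene mt-Nd1 fell (-0.46 ± 0.12). Cd274, which encodes PD-L1, had a log2 change of 1.43 ± 0.48 (adjusted p = 0.246) and Irf1 0.34 ± 0.29. Over the 6 classes where it was tested, Cd274 lay above 0 in 3 and below 0 in 3, with -1.25 ± 0.43 (adjusted p = 0.497) in B-like cells. Without WT 1, 17 genes passed and the calls ended for Bcl2a1a (1.35), Pim1 (-0.63), Fos (-0.44), H2-K1 (0.54), H2-Q7 (0.86), H2-D1 (0.38), Nfkbia (0.56) and mt-Nd1 (-0.39). Without IFNgR KO 2 they ended for Chil3 (-0.63), Bcl2a1a (1.28), H2-Q7 (1.28), H2-D1 (0.51), Cd9 (1.02) and mt-Nd1 (-0.46), and without IFNgR KO 1 for H2-D1 (0.43) and mt-Nd1 (-0.47). The count was 60 without WT 2 and 56 without IFNgR KO 1, and DESeq2 called 2 genes, both among the 37.

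In monocyte-like cells 8 lists were called, none with an estimated correlation (adjusted p from 0.541 to 0.719 with an estimated correlation). MHC class I antigen presentation had a median log2 change of 0.36 (13 of 16 above 0; 3 passed over all genes and 5 adjusted over the list alone), interferon-gamma response genes 0.34 (19 of 21; 0 and 0), complement and lipid-handling genes 0.45 (11 of 14; 1 and 5), NF-kB targets 0.27 (10 of 13; 2 and 3) and hypoxia and glycolysis 0.23 (14 of 18; 0 and 0). Immediate early genes (median -0.57; 1 and 6 of 18 lower), inflammatory myeloid genes (-0.40; 0 and 3 of 10) and mitochondrially encoded genes (-0.31; 1 and 7 of 12) were called lower. Only the immediate early call stood without each library in turn, with a median of -0.38 without WT 1. Without IFNgR KO 2 the medians of lost calls were 0.03 for interferon-gamma, 0.13 for MHC class I, 0.19 for complement and lipid-handling, 0.26 for NF-kB and -0.28 for mitochondrial genes. Without WT 1 they were 0.33, 0.22, 0.18 and -0.28 for interferon-gamma, MHC class I, NF-kB and mitochondrial genes and -0.26 for inflammatory genes, and the complement and lipid-handling median was 0.28. The complement and lipid-handling and the hypoxia calls ended without WT 2 (0.46 and 0.08) and without IFNgR KO 1 (0.34 and 0.14). The hypoxia median was 0.40 without IFNgR KO 2, and the NF-kB median 0.51 without WT 2 and 0.13 without IFNgR KO 1.

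Among dendritic classes, cDC2-like cells, marked by Cd209a and Clec10a, had 7 transcripts higher and 2 lower of 5997 tested. Ddit4 rose from 47.1 ± 1.34 to 139 ± 28.8 CPM (log2 change 1.53 ± 0.23, adjusted p = 0.00544), the lectin gene Cd209e from 3.40 ± 0.640 to 27.4 ± 1.98 CPM (3.0 ± 0.50, 0.0142), the interferon-inducible gene Mnda by 1.76 ± 0.29 and the nucleic acid sensor gene Zbp1 by 1.37 ± 0.25 (SD, n = 2). Ccl4, a chemokine for T cells and monocytes, fell from 142 ± 8.56 to 27.9 ± 8.0 CPM (-2.27 ± 0.24, 2.08e-04), and the fibronectin gene Fn1 fell by 1.97 ± 0.35 on the log2 scale. Axl, a receptor kinase, stood at -1.60 ± 0.33 (edgeR adjusted p = 0.0750), at -1.63 without WT 1 and at -1.65 without IFNgR KO 1. Type I interferon-stimulated genes had a median of 0.62 (24 of 25 above 0; 1 passed over all genes and 7 adjusted over the list alone), interferon-gamma response genes 0.63 (18 of 20; 0 and 4) and MHC class I genes 0.23 (13 of 16; 0 and 2). Inflammatory myeloid genes had a median of -0.79 (1 and 1 of 10 lower) and immediate early genes -0.56 (0 and 9 of 19 lower). T cell markers had a median of -1.49 in this class (0 of 7 above 0, adjusted p = 0.260) and regulatory T cell markers -1.18 (0 of 5, 0.325), neither called. Droplets with at least 5 T cell marker UMIs made up 4.03% and 17.6% of it in WT and 4.67% and 3.98% in IFNgR KO. All 5 calls ended with an estimated correlation (adjusted p from 0.393 to 0.888 with an estimated correlation). Without IFNgR KO 2, 6 genes passed, the calls of Cd209e (2.91), Mnda (1.71), Zbp1 (1.26), Fn1 (-2.51) and MHC class I genes (0.21) ended, and the interferon-gamma median was 0.22. The counts were 64, 44 and 54 without WT 1, WT 2 and IFNgR KO 1. The MHC class I median was 0.12, its call lost, without WT 1, 0.45 without WT 2 and 0.35 without IFNgR KO 1, and the interferon-gamma median 1.00 without WT 2. DESeq2 called 3 of the 9 genes.

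Migratory dendritic-like cells, marked by Ccr7 and Fscn1, had 11 transcripts higher and 10 lower of 2642 tested. With thinning to the same mean UMIs per cell 0 passed with edgeR, and with doublets kept 2. The redox gene Txndc17 rose from 309 ± 103 to 760 ± 32.1 CPM (log2 change 1.26 ± 0.23, adjusted p = 0.00391), Irf8, a transcription factor of dendritic cells, by 1.32 ± 0.27, the proteasome activator gene Psme1 by 0.76 ± 0.18 and the chemokine gene Ccl5 by 0.73 ± 0.17. Cd3g, a chain of the T cell receptor complex, fell from 218 ± 53.6 to 68.2 ± 0.555 CPM (-1.71 ± 0.32, 0.00426; SD, n = 2), and so did Lck (-2.85 ± 0.60), Cd3d (-1.27 ± 0.31), the GTPase gene Rac2 (-1.57 ± 0.28) and the annexin partner gene S100a10 (-1.35 ± 0.22). T cell markers were lower as a group (median -1.71, adjusted p = 4.24e-08), and markers of migratory dendritic cells higher (0.45, 8 of 9 above 0, 3 passed over all genes, 0.00120). Droplets with at least 5 T cell marker UMIs made up 23.8% and 26.8% of this class in WT and 9.38% and 9.59% in IFNgR KO, against 0.263%, 1.46%, 1.44% and 0.535% of monocyte-like cells. Without these droplets 0 genes passed with edgeR, 132 had an unadjusted p under 0.05, and this set was not run with DESeq2. The median of the migratory dendritic markers was then 0.13 (adjusted p = 0.0591). Interferon-gamma response genes had a median of 0.42 (11 of 12 above 0; 1 passed over all genes and 2 adjusted over the list alone), with an adjusted p of 0.792 with an estimated correlation. That list call ended without those droplets (0.23), without WT 1 (0.40) and without IFNgR KO 2 (0.26). Calls also ended without WT 2 for Rac2 (-1.11), Cd3g (-1.37) and Psme1 (0.68), without IFNgR KO 1 for Psme1 (0.70) and without IFNgR KO 2 for Irf8 (1.13) and Psme1 (0.84). The count was 85 without WT 1 and 34 without IFNgR KO 2, and DESeq2 called 4 of the 21 genes.

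In pDC-like cells, marked by Siglech, H2-Ab1 rose from 1054 ± 17.6 to 1643 ± 299 CPM (log2 change 0.64 ± 0.13) and Wdr89 fell (-0.61 ± 0.13; adjusted p = 0.0345 for both), while B2m, the light chain of MHC class I, stood at 0.45 ± 0.10 (0.0768). B2m stood at 0.57 without WT 2 and at 0.48 without IFNgR KO 2. The 2 of 3336 genes no longer passed without IFNgR KO 2 (0.45 and -0.42), and DESeq2 called 0. MHC class I genes had a median of 0.35 (15 of 17 above 0; 0 passed over all genes and 6 adjusted over the list alone) and ribosomal protein genes -0.21 (2 of 22 above 0; 0 and 0), both at an adjusted p of 0.604 with an estimated correlation. Both list calls ended without WT 1 (0.29 and -0.18) and without IFNgR KO 2 (0.32 and -0.15), and the ribosomal one also without WT 2 (-0.19). The counts of genes were 10, 12, 6 and 15 without WT 1, WT 2, IFNgR KO 1 and IFNgR KO 2. In cDC1-like cells, marked by Xcr1 and Clec9a, 0 of 3521 genes passed with edgeR, 208 had an unadjusted p under 0.05 and DESeq2 called 0. Fos had a log2 change of -0.89 ± 0.22 there, and the survival genes Bcl2a1a and Bcl2a1b 1.03 ± 0.27 and 1.27 ± 0.33. Without IFNgR KO 2 these stood at -1.05, 1.35 and 1.49, and without WT 1 the survival genes stood at 1.25 and 1.87.

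Lymphoid classes had few changed genes, Fos among them. In B-like cells Fos fell from 162 ± 40.6 to 64.2 ± 22.8 CPM (log2 change -1.31 ± 0.23, adjusted p = 0.0287), in CD4 T-like cells by 2.41 ± 0.50 on the log2 scale (0.0209) and in NK-like cells by 2.00 ± 0.32 (0.0461; SD, n = 2). B-like cells also had higher Hsp90b1, an endoplasmic reticulum chaperone (99.9 ± 16.0 to 231 ± 57.9 CPM, 1.28 ± 0.21, 0.00990), and higher Igkc, the immunoglobulin kappa constant gene (0.87 ± 0.12, 0.00125), which was named after its value was seen. Plasma cell markers were higher as a group in that class (median 1.02, camera adjusted p = 3.85e-04). In the 2132 B-like cells with fewer than 50 plasma marker UMIs, neither Hsp90b1 nor Igkc passed. There 0 genes were called higher and 1 lower with edgeR. Fos passed no longer in B-like cells without WT 1 (-0.97), nor in CD4 T-like cells without WT 1 (-2.77), WT 2 (-1.94) or IFNgR KO 2 (-2.66), and stood at -3.11 in NK-like cells without IFNgR KO 2. Counts were 3 of 4803 genes in B-like cells (8, 28, 27 and 20 without WT 1, WT 2, IFNgR KO 1 and IFNgR KO 2), 1 of 1996 in CD4 T-like cells (1, 2, 10 and 7) and 1 of 3822 in NK-like cells (23, 9, 13 and 64). DESeq2 called 1, 0 and 0. In NK-like cells Ifi27l2a, an interferon-induced gene, stood at 1.77 ± 0.32 (edgeR adjusted p = 0.0952). It stood at 2.00, 1.96 and 1.44 without WT 1, IFNgR KO 1 and IFNgR KO 2. Immediate early genes were called lower in these classes by camera: B-like (median -0.52, 1 of 15 past the threshold over all genes and 7 adjusted over the list alone), CD4 T-like (-0.62, 1 and 5 of 10) and NK-like (-0.56, 1 and 4 of 13). The adjusted p was 0.486, 0.957 and 0.878 with an estimated correlation. The median was -1.29, -0.37 and -1.07 in CD4 T-like cells without WT 1, WT 2 and IFNgR KO 2, and -0.28 and -0.96 in NK-like cells without IFNgR KO 1 and IFNgR KO 2.

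CD8 T-like cells had no gene past the threshold: 0 of 4677 passed with edgeR, 136 had an unadjusted p under 0.05, and DESeq2 called 3. The smallest p-values belonged to Ifitm1, an interferon-induced membrane protein, at 65.7 ± 2.76 CPM in WT and 6.11 ± 4.43 in IFNgR KO (log2 change -3.01 ± 0.43, adjusted p = 0.0826; SD, n = 2), and Dapl1, a gene of naive and memory T cells (-3.88 ± 0.57, 0.110). With 1 library left out these stood at -2.91 and -4.34 (WT 1), -3.02 and -3.13 (WT 2), -2.78 and -4.25 (IFNgR KO 1) and -4.34 and -2.85 (IFNgR KO 2). Ifng stood at -1.85 ± 0.48, Pdcd1, which encodes PD-1, at -0.45 ± 0.70, and the interferon-induced genes Ifi27l2a and Rtp4 at 1.08 ± 0.21 and 1.70 ± 0.42. Ifng was at -2.31 without WT 1 and -2.88 without IFNgR KO 2. Rtp4 was at 2.15 without WT 1 and 1.98 without IFNgR KO 1, and Ifi27l2a at 1.23 without IFNgR KO 1. Type I interferon-stimulated genes were called higher (median 0.79, 19 of 19 above 0; 0 passed over all genes and 2 adjusted over the list alone), as were interferon-gamma response genes (0.49, 13 of 15; 0 and 0) and MHC class II genes, which T cells of mice scarcely transcribe (0.60, 6 of 6; 0 and 0). Immediate early genes were called lower (-0.26; 0 and 0 of 16), and the adjusted p lay from 0.852 to 0.978 with an estimated correlation. The class held different subsets in each library: cluster L12, whose leading genes were Xcl1, Ccl3 and Ifng, made up 10.1% and 52.4% of it in WT and 26.8% and 3.17% in IFNgR KO. Cluster L9, led by Gzma and Gzmb, made up 13.2% and 3.17% in WT and 1.79% and 24% in IFNgR KO. Without WT 1 the calls ended for interferon-gamma (0.40), MHC class II (0.25) and immediate early genes (-0.11), without WT 2 for type I interferon (0.46) and interferon-gamma genes (0.45), and without IFNgR KO 2 for interferon-gamma (0.17) and immediate early genes (-0.29). The type I interferon median was 1.19 without WT 1 and 0.33 without IFNgR KO 2, the MHC class II median 1.12 and the immediate early median -0.41 without WT 2. Counts of genes were 33, 4, 35 and 8 without WT 1, WT 2, IFNgR KO 1 and IFNgR KO 2.

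Regulatory T-like cells, Lef1-high T cells and Klra7-high lymphoid cells, which were named by their leading genes, had 0 changed genes of 6773, 2958 and 3097 with edgeR, with 341, 125 and 216 at an unadjusted p under 0.05 and 0 by DESeq2. In regulatory T-like cells Fos stood at -1.58 ± 0.30 (adjusted p = 0.0927), Ncmap at -1.21 ± 0.23 (0.0927), the interferon-stimulated gene Ifit1 at -1.78 ± 0.38 (0.193), the metallothionein gene Mt2 at 1.17 ± 0.24 (0.176) and Pdcd1 at -0.33 ± 0.20. Without WT 1 Fos was at -1.83, Ncmap at -1.23, Ifit1 at -2.09 and Mt2 at 1.29 in these cells. Without IFNgR KO 1 Fos was at -1.56 and Mt2 at 1.35. Without IFNgR KO 2 Fos was at -1.60, Ncmap at -1.23, Ifit1 at -1.73 and Mt2 at 1.03. Their proliferation genes were called higher (median 0.35, 23 of 25 above 0, camera adjusted p = 0.990 with an estimated correlation), a call that ended without IFNgR KO 1 (0.13). Of these genes 0 passed over all genes and 0 adjusted over the list alone. Cluster L10, with Top2a and Stmn1 among its leading genes, made up 16.8% and 14.5% of the class in WT and 22.9% and 16.0% in IFNgR KO. Whether that share accounts for the call was not tested. In Lef1-high T cells MHC class II genes were called higher (median 0.88, 5 of 6 above 0; 0 passed over all genes and 0 adjusted over the list alone) and immediate early genes lower (-0.56; 0 and 1 of 12), both at an adjusted p of 0.998 with an estimated correlation. The MHC class II call ended without WT 1 (0.55), WT 2 (0.70), IFNgR KO 1 (0.31) or IFNgR KO 2 (1.17), and the immediate early call without WT 1 (-0.19) or IFNgR KO 1 (-0.35), with a median of -1.25 without IFNgR KO 2. Xcl1, a chemokine for cross-presenting dendritic cells, stood at -0.82 ± 0.18 (adjusted p = 0.236) in Klra7-high lymphoid cells. Their immediate early genes were called lower (median -0.43; 0 and 3 of 13; adjusted p = 0.790 with an estimated correlation), a call that ended without WT 2 (-0.30) and IFNgR KO 1 (-0.35), with a median of -0.85 without IFNgR KO 2. Counts without WT 1, WT 2, IFNgR KO 1 and IFNgR KO 2 were 21, 5, 16 and 56 in regulatory T-like cells, 3, 6, 4 and 5 in Lef1-high T cells and 10, 3, 6 and 14 in Klra7-high lymphoid cells.

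Across the 13 tested classes the interferon and stress lists leaned one way more often than not. Interferon-gamma response genes had a median above 0 in 12 classes, 5 of them called higher, and MHC class I genes in 12, 4 of them called. Type I interferon-stimulated genes lay above 0 in 10 classes (3 called), and MHC class II genes in 7 of 11 (3 called). Immediate early genes lay below 0 in 13 classes (9 called lower), and inflammatory myeloid genes in all 4 classes tested (3 called lower). These medians share the same 4 libraries and are not independent of one another, and none of the 38 list calls held with an estimated correlation. That test also missed a simulated shift of 1 log2 unit in macrophage-like cells, so a lost call does not show that a list is unchanged. Lists of T cell exhaustion, naive and memory T cells, cytotoxic effectors, mature NK cells, ILC1, regulatory T cell effectors, alternatively activated macrophages, interferon receptors and chemokines were called in no class.

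**Figure D3:**
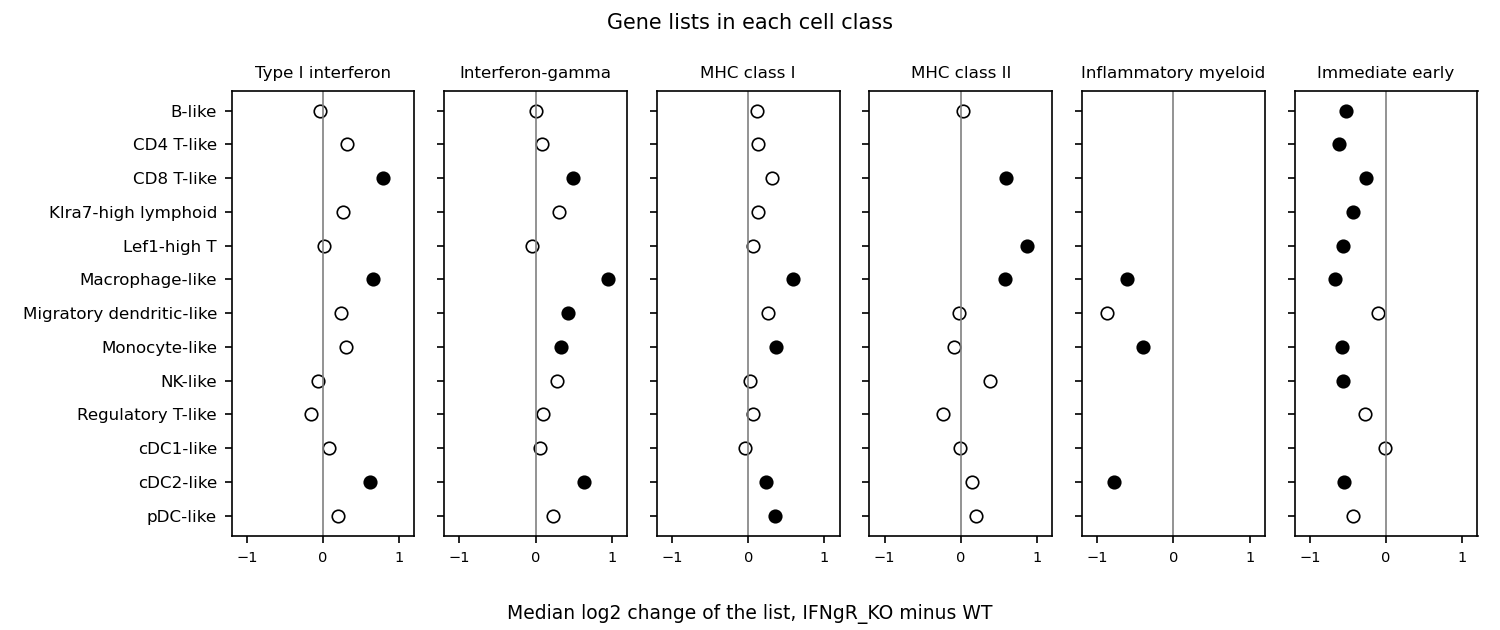
Median log2 change (IFNgR KO minus WT) of 6 gene lists in each of the 13 tested classes; filled points were called by camera with a preset correlation, open points were not, and a missing point means that under 5 members were tested. The interferon-gamma median is largest in macrophage-like cells (0.95), and the immediate early medians lie below 0 in 13 classes.

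A few transcripts lay on the same side of 0 in every class, mostly without passing the test. Of 1498 genes tested in all 13 classes, 72 had one sign throughout (43 higher and 29 lower in IFNgR KO); the classes share the same 4 libraries, so a difference between libraries or free RNA gives shared signs too. Fos had a median log2 change of -1.31 over the classes (range -2.41 to -0.64) and passed in 4 of them. Gm42418 (median 0.93, range 0.44 to 1.14) and AY036118 (1.70, 1.11 to 1.82), which overlap ribosomal RNA repeats, passed in 3 and 2 classes. Malat1, a nuclear noncoding RNA, lay above 0 in 13 classes (median 0.31), and Wdr89 (-0.45) and mt-Nd1 (-0.38) below 0 in 13. Reads of repeats and near copies are assigned with uncertainty.

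**Figure D4:**
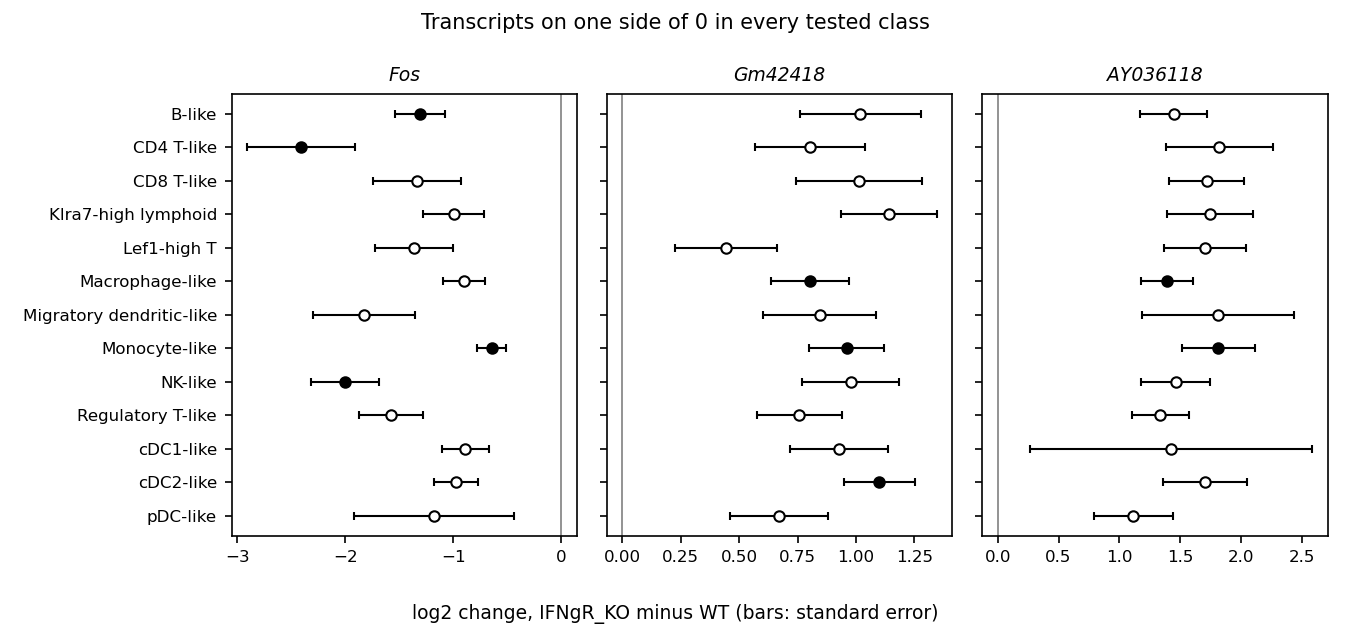
Log2 change (IFNgR KO minus WT) of Fos, Gm42418 and AY036118 in each of the 13 tested classes. Bars are approximate standard errors calculated from the F statistic, and filled points passed the test. Fos lies below 0 and both other transcripts above 0 in all 13 classes.

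Whether the groups differed more in the myeloid than in the T cell compartment was tested directly, with the library as a block. Ly6a, the gene of the stem cell antigen Sca-1 that interferons induce, was the 1 gene of 9850 that passed (difference in log2 change 1.61 ± 0.24, adjusted p = 0.0253). In summed monocyte-like and macrophage-like cells it stood at 46.2 and 58.6 CPM in WT and 274 and 138 in IFNgR KO, a log2 change of 1.96, and in summed T cells at 589 and 1002 against 1069 and 826 CPM, a change of 0.25. A total of 335 genes had an unadjusted p under 0.05, and DESeq2 called 0. With edgeR 0 passed at a CPM of at least 10, with doublets kept, at resolutions 0.5 and 2.0 or with all variable genes. The counts were 20, 2, 55 and 0 without WT 1, WT 2, IFNgR KO 1 and IFNgR KO 2, and Ly6a did not pass without WT 2 or IFNgR KO 2. More myeloid cells of IFNgR KO held T cell RNA as well, a difference in shares that was not tested. Cells with a T cell marker UMI made up 7.23% and 12.7% of macrophage-like cells in WT and 14.8% and 21.1% in IFNgR KO, and 5% and 7.31% against 12.9% and 19.3% of monocyte-like cells. T cell markers had a median of 0.54 in the compartment (8 of 8 above 0, adjusted p = 0.0873). In macrophage-like cells alone the log2 change of Ly6a was 1.94 ± 0.34 (adjusted p = 0.111), and 2.12 ± 0.34 (0.0682) without cells carrying a T cell marker UMI. Of the lists, 7 differed, with interferon-gamma response genes 0.64 higher in the myeloid compartment at the median (30 of 32 members above 0, camera adjusted p = 5.87e-10; 0 passed over all genes and 5 adjusted over the list alone). None differed with an estimated correlation (adjusted p = 0.580 for that list with an estimated correlation). The number of lists was 4 without IFNgR KO 1 and 3 without IFNgR KO 2, and the interferon-gamma difference was 0.35 without IFNgR KO 2.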

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

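Of the tests below, those of handling, of UMIs per cell, of the tumor genotype, of the macrophage clusters and of free RNA were chosen only after the result was seen. The compartment test asked whether IFNgR KO minus WT differs between the monocyte-like and macrophage-like cells and the T cells, and a difference between these compartments brought the next results here. Ly6a, an interferon-induced surface antigen, changed more in the myeloid compartment by 1.61 ± 0.24 on the log2 scale (edgeR adjusted p = 0.0253), though not without WT 2 or IFNgR KO 2. T cell markers were above 0 in that compartment too (median 0.54, 8 of 8), though not called (camera adjusted p = 0.0873). Interferon-gamma response genes differed by 0.64 at the median (30 of 32 members above 0), type I interferon-stimulated genes by 0.16 (24 of 37), MHC class I genes by 0.31 (18 of 19) and MHC class II genes by 0.50 (11 of 11). Interferon receptors and JAK-STAT genes differed by 0.21 (9 of 12), regulatory T cell effector genes by 1.01 (13 of 15) and complement and lipid-handling genes by -0.27 (4 of 19 above 0). The adjusted p with camera ran from 5.87e-10 to 0.0345, and from 0.580 to 0.797 with an estimated correlation. Regulatory T cell effector genes are read mostly in T cells, whose makeup differed between libraries.

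Immediate early genes such as Fos had lower values, and Gm42418 and AY036118 higher values, in IFNgR KO in nearly every class. A difference in UMIs per cell is argued against. The IFNgR KO libraries had means of 3186 and 2559 UMIs per cell, on both sides of 2705 and 2775 in WT, yet the immediate early median in all cells, -0.70, was -0.57 without IFNgR KO 1 and -0.77 without IFNgR KO 2. Thinning scales all genes of a library alike and decides nothing here. A difference in handling or library preparation stays open. The immediate early list differed between compartments by -0.12 at the median, but its members went both ways (8 of 19 above 0, median size 0.41), so that value decides nothing. Fos itself had a log2 change of -1.71 in T cells and -0.77 in the myeloid compartment (difference 0.96 ± 0.25, not past the threshold). An effect of the tumor genotype on all immune cells, which would give the same sign in all 13 classes, cannot be told apart from handling, because the labels give no batch. Which of these may have caused the pattern stays open.

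Interferon-response genes such as Isg15 and Gbp7 were higher in macrophage-like cells of IFNgR KO, with an interferon-gamma median of 0.95. The list was not called with an estimated correlation or by fry (adjusted p = 0.412 and 0.334). Without WT 1 Isg15 stood at 0.90 and Gbp7 at 1.64, neither past the threshold. Isg15 passed in neither cluster (0.90 ± 0.24 in cluster 4 and 0.96 ± 0.20 in cluster 9, edgeR adjusted p = 0.197 and 0.0903). Gbp7 passed in cluster 4 (1.38 ± 0.28, 0.0269) and was not tested in cluster 9. T cells captured with macrophages are argued against, since the median was 0.96 in cells without a T cell marker UMI (0.53 to 1.29 when 1 library was left out). With all libraries most of the change was also seen inside the clusters, with a median of 0.80 in cluster 4 and 0.70 in cluster 9. Without IFNgR KO 2 these were 0.27 and 0.12, but the class itself was then at 0.36. How far a shift of cells between clusters contributed therefore stays open. A shift shared by the libraries in every class stays open too, with a difference between compartments of 0.64 that was 0.35 without IFNgR KO 2. An effect of the tumor genotype on macrophages stays open and was not tested. Ifng itself had log2 changes of -1.85 in CD8 T-like, -1.01 in regulatory T-like and -0.58 in NK-like cells, none past the threshold.

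T cell transcripts such as Cd3g and Lck were lower in migratory dendritic-like cells of IFNgR KO. Free RNA of T cells is argued against, as droplets with at least 5 T cell marker UMIs were at least 6.52 times as frequent in this class as in monocyte-like cells of the same library. T cells captured in the same droplets remain a candidate explanation: without such droplets the called transcripts other than T cell markers had a median of -0.55, against -1.26 with them (-0.18 to -0.52 when 1 library was left out). Those droplets had medians of 6184.5, 6496, 5978 and 7297 UMIs, against 3448, 2914.5, 3543 and 3143 in the others. Whether the pairs formed in the tumor or in the instrument stays open.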

How the results depend on the processing

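The alternatives by single cluster, without CD8 T-like cells and without cells carrying plasma or T cell marker UMIs were chosen after seeing the data. Of 5843 comparisons of named genes with an alternative, 5177 kept direction and side of the threshold, 281 lost a call, 380 gained one and 5 reversed. Of 948 for lists 731 kept theirs and 217 lost it. None of 183 comparisons of shares passed, as in the main test, although the values moved: without 1 library the log2 change ran from 0.07 to 2.12 for CD8 T-like, -1.24 to 0.94 for regulatory T-like, -0.21 to 1.49 for CD4 T-like, -0.17 to 1.52 for cDC1-like and -0.64 to -0.48 for macrophage-like cells. Counts of genes stayed within 1.5 times in 132 of 290 cases.

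In the order all cells, class total, macrophage-like, migratory dendritic-like, monocyte-like, cDC2-like and the compartment difference, DESeq2 called 29, 37, 24, 4, 2, 3 and 0 genes. With no filter on low counts these were 76 for all cells, 391 for the total, 168 for macrophage-like, 49 for migratory, 46 for cDC2-like cells and 11 for the compartment difference. A CPM of at least 10 gave 44 for migratory cells and 0 for the compartment difference. The replicate number as block gave a total of 316, with 84 for migratory, 62 for monocyte-like and 49 for cDC2-like cells; in all cells the same-number correlation was only 0.0954, and the compartment test has no such result. Library sizes only gave 5 for cDC2-like cells. With doublets kept the total was 83, with 2 for migratory, 17 for monocyte-like and 4 for cDC2-like cells and 0 for the compartment difference. At least 1000 UMIs and 500 genes gave 58 for monocyte-like cells, and thinning to the same mean UMIs per cell in every library 0 for migratory cells. The compartment difference had 0 at resolution 0.5, at resolution 2.0 and with all variable genes. Resolution 2.0 gave 11 for monocyte-like cells, and all variable genes 9 for macrophage-like and 11 for migratory cells. Immune classes only gave 2 for all cells. These counts of 0 are from edgeR except the one by DESeq2, and 335 genes had an unadjusted p under 0.05 in the compartment test. The cause was not tested.

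In CD8 T-like cells Fcer1g (-0.76), H2-Eb1 (-1.84) and H2-Aa (-1.71) reversed at resolution 2.0 and Ifit1 with all variable genes (-0.83); Cxcl3 reversed in macrophage cluster 4 (0.25). The cause was not tested. Macrophage cluster 4 had 17 changed genes, cluster 9 had 8, and macrophage-like cells without a T cell marker UMI 27. Migratory cells without T cell marker droplets had 0 (132 at an unadjusted p under 0.05); fewer cells and genes were tested in each. Estimated correlation and fry called 0 lists in all cells and 0 in the classes, with the interferon-gamma median in macrophage-like cells at 0.95 under both (adjusted p = 0.412 and 0.334), since they change only the test.

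When 1 library was left out, its group's other library was assumed to vary like the other group. The class total was 126 with all libraries and rose with each removal, so calls gained then are no support for a gene. The counts ran from 0 to 404 for all cells, 235 to 555 for the total, 20 to 297 for macrophage-like, 15 to 85 for migratory, 17 to 60 for monocyte-like and 6 to 64 for cDC2-like cells, and 0 to 55 for the compartment difference. Called lists ran from 5 to 12, from 35 to 61 in the classes and from 3 to 10 between compartments, and the interferon-gamma median from 0.36 to 1.24. Sign changes of 126 values that had not passed, within 1 SE, are counted as the same. The second file set was identical and gave no alternative.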

Other observations

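The tests within single clusters were chosen only after the result was seen. In cluster L0 of the regulatory T-like cells, led by Izumo1r and Ctla4, 23 of 3406 genes passed with edgeR, 13 higher and 10 lower in IFNgR KO. The groups did not overlap for 11 of the higher and 10 of the lower genes. Fos, AY036118, Cd74, Psmb9, mt-Atp8, Gm9493, Rps12-ps3 and Rps26-ps1, all among the 23, lay on the same side of 0 in all 13 tested classes. Gimap7, a GTPase of lymphocyte survival, rose from 199 to 426 CPM (log2 change 1.01 ± 0.19, adjusted p = 2.62e-04) and the glycolysis gene Tpi1 from 223 to 414 CPM (0.96 ± 0.19). Pglyrp1, a peptidoglycan recognition gene, rose by 0.84 ± 0.17 and H2-Ab1 by 1.38 ± 0.36. H2-Ab1 went from only 33.3 to 92.8 CPM, against 1916 and 2936 CPM in macrophage cluster 4, and free RNA was not subtracted. Fos (-1.68 ± 0.38), Jun (-1.60 ± 0.37) and the chemokine receptor gene Cxcr6 (-1.64 ± 0.41) fell. Hypoxia and glycolysis genes had a median of 0.61 (14 of 16 above 0; 2 passed over all genes and 7 adjusted over the list alone; adjusted p = 0.904 with an estimated correlation). In cluster L3 of the CD4 T-like cells Ccl5 rose from 4303 to 7776 CPM (0.88 ± 0.15, adjusted p = 1.12e-05), and in cluster L12 of the CD8 T-like cells Dapl1 fell from 278 to 44.6 CPM (-2.57 ± 0.38, 0.0228). Most lymphoid clusters had no call. Clusters L4 and L10 of the regulatory T-like cells had 0 of 3003 and 4134 genes with edgeR (162 and 147 at an unadjusted p under 0.05). Clusters L2, L5, L6, L7, L8 and L11 of other classes also had 0 (42 to 106 at an unadjusted p under 0.05), and DESeq2 was not run on single clusters. These clusters were not tested without single libraries.

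Melanoma-like cells among the sorted CD45+ cells entered the sum of all cells and no test within a class. There were 10 and 5 in the WT libraries and 8 and 4 in the IFNgR KO libraries, led by the pigment genes Dct, Mlana and Pmel. They held 4, 1, 4 and 0 UMIs of Ptprc, the gene of CD45. The 27 cells carried B2m at 671 and 779 CPM in WT and 580 and 607 in IFNgR KO, and Dct at 8505 and 6767 against 8324 and 7322. H2-D1 stood at 126 and 110 CPM in WT and 191 and 226 in IFNgR KO, and H2-K1 at 51.1 and 82.5 against 97.4 and 86.8, the opposite way from B2m, on 5 to 45 UMIs per library. Interferon-gamma response genes together stood at 301 (exact 95% Poisson interval 245 to 366) and 312 (216 to 436) in WT and 322 (254 to 403) and 312 (185 to 494) in IFNgR KO. The intervals cover counting error only and overlap for that list. No difference between the groups was tested in these cells.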
